A study of Homo sapiens with 6 samples.

How the data were processed

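Nascent-strand sequencing (NS-seq) enriches short, newly made DNA that starts at replication origins, after size fractionation and exonuclease digestion of DNA without an RNA primer. It was applied to U2OS, a human osteosarcoma cell line, transfected with a control siRNA (gl3) or with an siRNA against ORCA. ORCA, the product of LRWD1, binds the origin recognition complex and helps to hold it on chromatin. The labels list 4 nascent-strand samples, 2 control and 2 siORCA, and 2 genomic DNA samples, 1 per transfection, which were not analysed here. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

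Reads were processed with BWA, SAMtools and MACS2 on the T2T-CHM13 genome build, per the submitters' processing notes, with versions and settings not given in the sources used here. Each sample has its own deposited list of broad peaks, so peaks were called per sample and not on pooled replicates. Each deposited peak carries a position, a score, a fold enrichment over background as a linear ratio, and a −log10 p and a −log10 q. The score equals the whole part of 10 times the −log10 q in all but 81 of 945863 peaks. The lowest −log10 q in any deposited list is 1.303, close to a q of 0.05. Whether the genomic DNA samples served as background for the caller is not given in the sources used here. The lists hold no read counts, so sequencing depth is unknown, and the number and total length of peaks called in a sample can move with depth as well as with origin use.

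From the lists, the number of peaks, the covered length (the sum of peak lengths), the median width and the median of the authors' fold enrichment were computed per sample. Fold enrichment was used to describe and rank peaks within a list, and the lists' medians were set side by side as descriptions of lists whose depth is unknown. Samples were compared in pairs by the Jaccard index, which is the length shared by both lists over the length of their union, and by the share of peaks that overlap by at least 1 bp. The largest Wilson 95% margin of such a share is 0.384 percentage points, which covers counting error only. All 4 lists were merged into regions wherever peaks touched or overlapped, and each region was scored as present or absent in each sample. Regions in both siORCA samples and neither control sample are called gained, and those in both control samples and neither siORCA sample are called lost. The same counts were made for the other ways of splitting 4 samples into pairs.

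For positions along chromosomes, the length covered by peaks was summed in 1 Mb windows, and log2 of that length plus a pseudocount of 1000 bp, over the total covered length of the sample, was compared between groups with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, Benjamini-Hochberg adjustment, threshold 0.05). Fold changes of windows are on this scale, which understates the change of sparse windows. Windows with a mean of at least 5 kb covered over the 4 samples entered the test, which left 2464 of 3132. The procedure was tested on simulated data for the comparison of siORCA with control over 2464 windows, with 50 windows changed at each size. It recovered 2% of windows changed by a log2 of 0.5, 50% of those changed by 1, 96% of those changed by 2 and 100% of those changed by 3, with 5 false calls among 129. The simulated noise was drawn independently for each window and sample. In the real samples a split that crosses the groups called 78 windows, so structure is shared across windows and these rates may not hold for them. Single values were compared with a two-sided exact permutation test, whose smallest possible p with 2 against 2 samples is 0.33. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

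Windows were named by a rule set before the data were examined: those past the threshold with no overlap between the groups (up to 5 each way), and, if fewer pass, the 3 each way with the smallest p. For single peaks the rule took the 3 with the highest fold enrichment in a control list that were in all 4 lists, read here as 3 from each control list, and the 3 widest gained and 3 widest lost regions. The alternatives tried were a stricter list (−log10 q of at least 3), lists shortened from the weakest peak to the same covered length, each replicate left out, the replicate number as a block, an overlap that takes in most of the interval, merging over gaps of 1 kb, median centring, no filter, a pseudocount 5 times larger, 250 kb windows and, chosen after seeing the data, cyclic loess over windows and a crossed block. No genome sequence or gene annotation of T2T-CHM13 was used here. The planned comparisons by gene, gene list, annotation class and sequence motif were therefore not run, and named positions carry no gene annotation. Of the sequence contexts, only the share of covered length within 50 kb of chromosome ends was computed, with the last covered base standing in for the end.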

Results

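NS-seq peaks, which mark DNA around active replication origins, were listed for 2 control and 2 siORCA samples of U2OS cells. The comparison asks how origin activity differs when ORCA, a partner of the origin recognition complex, is targeted by siRNA. The assay reads DNA, so the level of ORCA itself could not be checked. The lists held 181215 peaks in control 1, 235865 in control 2, 330265 in siORCA 1 and 198518 in siORCA 2. Sequencing depth is unknown because the lists hold no read counts.

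Peaks covered 58.5 Mb of the genome in control 1, 67.1 Mb in control 2, 86.2 Mb in siORCA 1 and 64.0 Mb in siORCA 2, between 1.88% and 2.77% of the assembly. The mean covered length was 62.8 ± 6.07 Mb in control and 75.1 ± 15.7 Mb in siORCA (SD, n = 2 each; exact permutation test, two-sided, p = 0.667). The mean number of peaks was 208540 ± 38643 in control and 264392 ± 93159 in siORCA (SD, n = 2 each; exact permutation p = 0.667). The siORCA 2 list lay between the control lists in both number and length, so the groups overlapped and the difference was within the spread between replicates. With only peaks of a −log10 q of at least 3 the groups did not overlap, at 65012 and 97973 peaks in control and 213328 and 112803 in siORCA, covering 29.2 ± 6.04 Mb against 52.3 ± 15.9 Mb (SD, n = 2 each; exact permutation p = 0.33 for both, the smallest this design allows). In the full lists without siORCA 1, the difference in number (siORCA minus control) turned to −10022 peaks.

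The median width was 202.5 ± 19.1 bp in control and 189.5 ± 31.8 bp in siORCA (SD, n = 2 each; exact permutation p = 0.667), and the groups overlapped. The median of the authors' fold enrichment was 3.82 in control 1, 3.94 in control 2, 4.51 in siORCA 1 and 4.21 in siORCA 2. Both siORCA lists thus had higher medians than both control lists (3.88 ± 0.0908 against 4.36 ± 0.209, SD, n = 2 each; exact permutation p = 0.33, the smallest this design allows). Peaks with a −log10 q of at least 3 made up 35.9% and 41.5% of the control lists and 64.6% and 56.8% of the siORCA lists. Among those peaks alone the median fold was 5.01 ± 0.0109 in control and 5.25 ± 0.365 in siORCA, and the groups overlapped (SD, n = 2 each; exact permutation p = 1.0). Each list was called by itself, so these values describe the lists and depend on their unknown depth.

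The strongest control peaks that were present in all 4 lists ranged from 123 to 807 bp in width. On T2T-CHM13, the peak with the highest fold enrichment in control 1 was on chromosome 18 from 80187394 to 80188200, at 214-fold in that list. It was followed there by a peak on chromosome X from 151138987 to 151139361 at 183-fold, and one on chromosome 16 from 29590731 to 29591450 at 170-fold. In control 2, the highest was on chromosome 15 from 72763861 to 72763987 at 154-fold. The site on chromosome X came next at 144-fold, and a peak on chromosome 3 from 56597311 to 56597433 at 125-fold was the third. In the siORCA 1 and siORCA 2 lists, the chromosome 18 site ranked 2 and 6, the chromosome 16 site 8 and 2, the chromosome 15 site 107 and 5, the chromosome 3 site 932 and 36, and the chromosome X site 974 and 42. These peaks were chosen for a high fold in a control list, and the lists differ in length and have an unknown depth. The ranks therefore do not test for a change.

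Samples shared peaks far more than randomly placed intervals of the same total length would, by 12.9-fold to 23.0-fold over the 6 pairs, but overlap did not follow the groups. The Jaccard index was 0.187 between the 2 control samples and 0.282 between the 2 siORCA samples. The highest of all pairs, 0.291, joined control 1 with siORCA 2, and the lowest, 0.185, joined control 2 with siORCA 1. The mean within groups exceeded the mean between groups by 0.0065, less than the SD of 0.0459 over the 6 pairs. Strong peaks were shared most. On average over the 4 samples, 72.3% of peaks in the strongest of 4 equal parts of a list overlapped another sample's peaks, against 25.7% in the weakest.

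**Figure D1:**
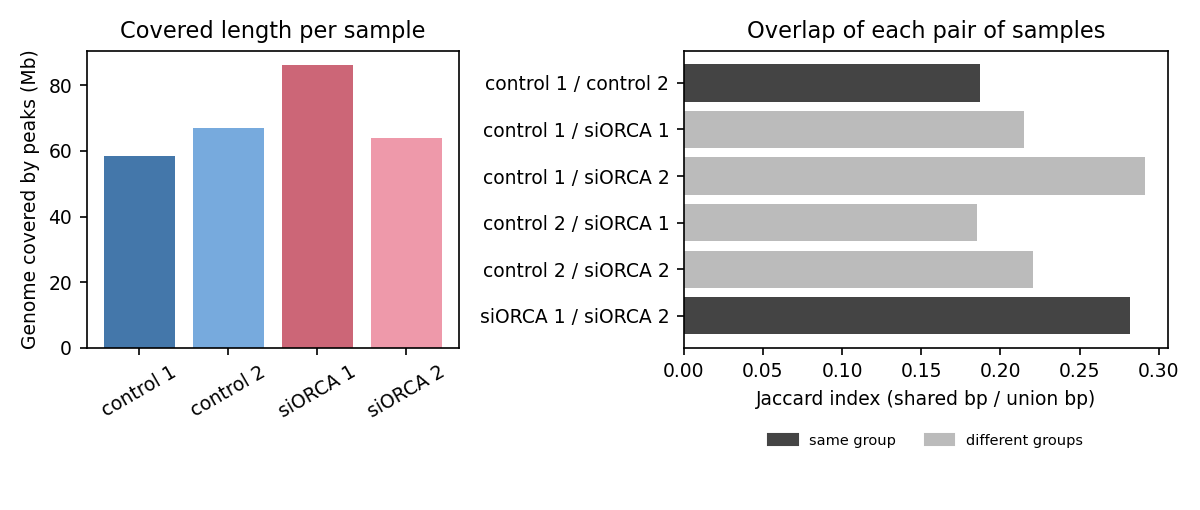
Left, genome length covered by peaks in Mb for each of the 4 samples (1 bar per sample). Right, Jaccard index (shared length over union length) of each of the 6 pairs of samples, with pairs of the same group in dark grey. siORCA 1 covers the most, at 86.2 Mb, and the highest index, 0.291, joins a control with an siORCA sample.

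The 4 lists merged into 535576 regions, of which 57130 (10.7%) were found in all 4 samples and 322008 (60.1%) in 1 sample only. Regions gained in siORCA numbered 29110 and covered 9.59 Mb, and regions lost numbered 8957 and covered 3.42 Mb, a ratio of 3.25. Pairs that cross the groups also had regions of their own, 23073 in control 2 and siORCA 1 only and 15181 in control 1 and siORCA 1 only. With all lists at the same covered length, 17838 regions were gained and 11029 lost, a ratio of 1.62. The other splits then gave ratios of at most 1.38. With the stricter list, 26435 regions were gained and 1974 lost, a ratio of 13.4, against at most 3.04 in the other splits. With gaps of 1 kb merged the ratio was 2.61, below the 3.45 of another split. With 3 splits, no share of splits under 0.33 can be reached. Leaving out siORCA 2 gave 177147 gained regions, and leaving out control 1 gave 104756 lost regions, which are then those of a single sample.

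The widest gained region lay on chromosome 8 from 8891056 to 8893167. It was covered over 2112 bp in siORCA 1 and 274 bp in siORCA 2. The next was on chromosome 3 from 10702445 to 10704516, covered over 1701 bp and 1530 bp in the same samples. A region on chromosome 9 from 146958035 to 146960099 was covered over 2065 bp and 515 bp. The widest lost region was on chromosome 6 from 162204148 to 162206557, with 2410 bp covered in control 1 and 193 bp in control 2. Regions on chromosome 8 from 43027697 to 43030079 and on chromosome 3 from 166803925 to 166806020 were 2383 bp and 2096 bp wide. In 5 of these 6 regions, 1 sample of the group covered far more than the other, the exception being the gained region on chromosome 3.

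**Figure D2:**
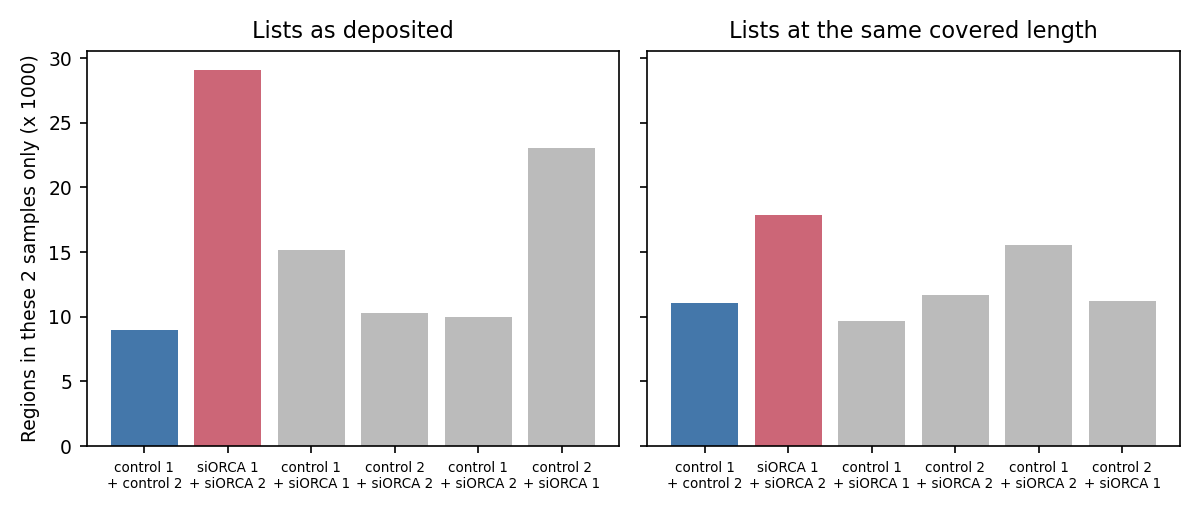
Number of merged regions (axis in units of 1000) found in exactly the 2 samples named under each bar, for the lists as deposited (left) and for lists at the same covered length (right). Blue marks control, red siORCA, and grey the pairs that cross the groups. The siORCA pair is highest on both sides, at 29110 and 17838 regions.

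Relative to the total covered length of each sample, 2 of 2464 windows of 1 Mb were higher in siORCA. On chromosome 10 from 43 to 44 Mb, peaks covered 30.5 ± 1.01 kb in control and 71.1 ± 0.573 kb in siORCA (SD, n = 2 each), a log2 difference of 0.95 with an SE of 0.20 (limma, adjusted p = 0.0281). On chromosome 1 from 143 to 144 Mb, they covered 11.8 ± 2.29 kb and 31.7 ± 3.06 kb, a log2 difference of 1.11 with an SE of 0.25 (limma, adjusted p = 0.0365). Both siORCA samples lay above both control samples in each window. The lengths in kb and their SDs are given before division by each sample's total, whereas limma tested the shares. The siORCA values on chromosome 10 are near equal in kb, but those samples cover 86.2 and 64.0 Mb in all. Their shares therefore differ more than the SD of 0.573 kb implies. No window passed as lower (0 in limma), and 76 windows had an unadjusted p under 0.05 in limma, a smaller share than the 0.05 that chance gives. The other splits gave 17 and 414 such windows. The share was above 0.05 with a pseudocount 5 times larger (157 of 2464) and at matched list size (162 of 2236). At that size the other splits gave 13 and 194. Of the 76, 30 were higher in siORCA, against 44 of 68 after cyclic loess and 14 of 157 with a pseudocount 5 times larger. The balance of directions thus moved with the scaling. Groups did not overlap in 30.7% of windows, where chance alone gives 33.3%, with siORCA above control in 267 and below in 490, and the median log2 difference over all windows was −0.09. Neither call held with the stricter list, median centring, a pseudocount 5 times larger or the replicate number as a block (0 windows called in each). The same was true of cyclic loess (0 called), chosen after seeing the data. In these settings the log2 differences were at least 0.85 on chromosome 10 and at least 0.88 on chromosome 1. Windows called as higher numbered 2 with no filter and 3 with the crossed block, also chosen after seeing the data. No window of 250 kb was called (0), and 1 of 1 Mb was left at matched list size. Without siORCA 1 both windows passed, among 18 called as higher and 64 as lower. Neither passed without control 1, without control 2 (0 windows called each) or without siORCA 2 (1 other window called). With each sample left out in turn, the log2 difference ran from 0.74 to 1.16 on chromosome 10 and from 0.99 to 1.23 on chromosome 1. Each of these fits leaves 1 sample in a group, so its calls rest on the spread of the other group and of other windows.

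Of the windows that did not pass, those with the smallest p above control were the next 2 on chromosome 10, from 44 Mb (log2 difference 0.66) and from 45 Mb (0.55), and one on chromosome 14 from 53 Mb (0.90). Those below control were on chromosome 4 from 189 Mb (−0.95), chromosome 16 from 20 Mb (−0.68) and chromosome 21 from 34 Mb (−0.75). All 6 had an adjusted p of 0.930 in limma. Without siORCA 1, which leaves 1 siORCA sample, the log2 differences were 0.88, 0.71 and 0.95 for the windows above control. For those below control they were −1.15, −1.01 and −1.19, in the order named. Without siORCA 2, which also leaves 1 siORCA sample, all were smaller in size. They were 0.43, 0.39 and 0.86 above control and −0.76, −0.345 and −0.31 below control, in the same order. In the window on chromosome 21 the groups overlapped. Over chromosome 10 from 43 to 46 Mb, 590 and 509 peaks were listed in siORCA 1 and siORCA 2, against 330 and 369 in control 1 and control 2. These counts come from lists of 330265, 198518, 181215 and 235865 peaks, in that order. Relative to list size, siORCA 1 had no more peaks in this stretch than control 1. By share of covered length, the stretch held 0.261% and 0.344% in siORCA 1 and siORCA 2, against 0.191% and 0.172% in control 1 and control 2. In 25 of 30 bins of 100 kb there, both siORCA samples had a larger share of their covered length than both control samples. In the next 3 Mb this held in 10 of 27 bins, and over the genome in 14.5% of bins. On chromosome 1 from 142 to 144 Mb it held in 14 of 16 bins. Each stretch joins a called window with its neighbours that were higher at an unadjusted p under 0.05, a rule chosen after the values were seen, so a high share of such bins is partly built in.

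**Figure D3:**
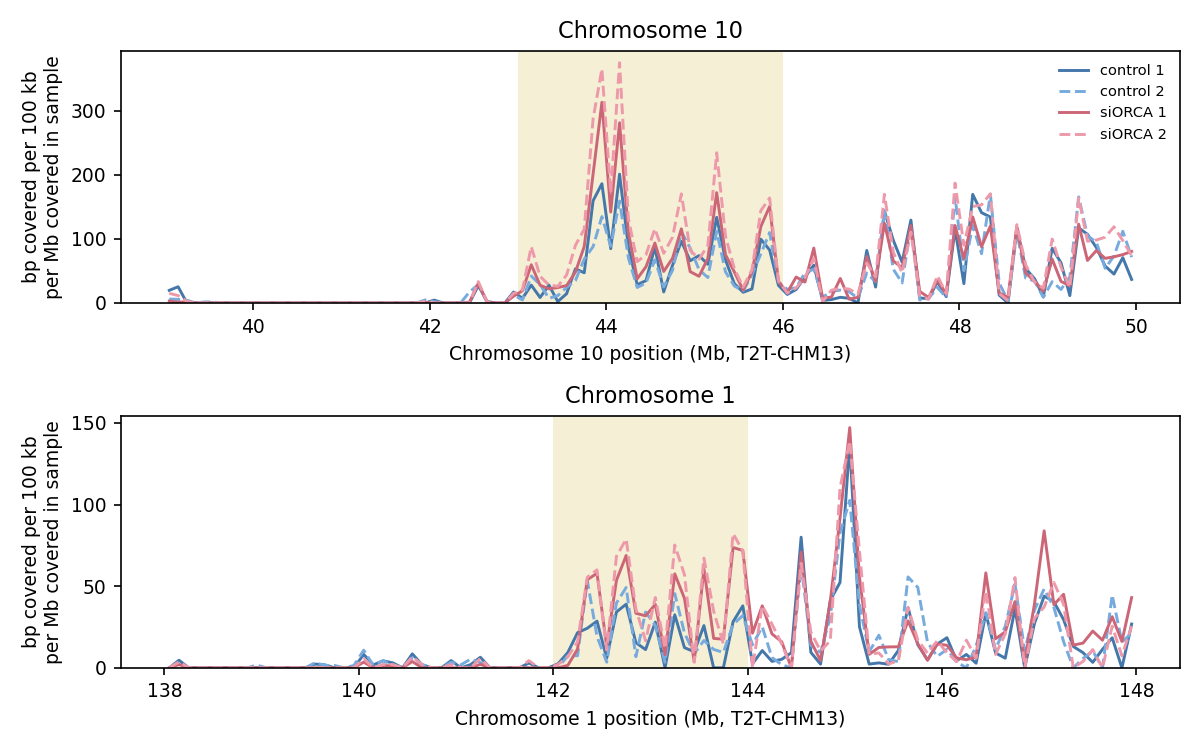
Length covered by peaks in bins of 100 kb, in bp per Mb covered in the whole sample, along chromosome 10 (top) and chromosome 1 (bottom), with 1 line per sample. The shaded stretches, 43 to 46 Mb and 142 to 144 Mb, hold the windows that passed the test, and both siORCA lines run above both control lines in most bins there, 25 of 30 on chromosome 10.

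Shares of covered length by chromosome differed little between groups. Chromosomes 7, 10, 15 and 20 had a larger share in both siORCA samples than in both controls, and chromosomes 3 and 11 a smaller one. On chromosome 10 the share was 4.91 ± 0.140% in control and 5.18 ± 0.151% in siORCA (SD, n = 2 each; exact permutation p = 0.33, 1.0 after Benjamini-Hochberg adjustment over 23 chromosomes). On chromosome 11 it was 5.92 ± 0.0241% and 5.63 ± 0.0466%. Chance alone gives 7.67 such chromosomes of 23, above the 6 seen. Leaving out siORCA 1 raised that count to 18, and leaving out control 1, control 2 or siORCA 2 raised it to 16, 11 or 13, since a single sample overlaps less often.

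Within 50 kb of chromosome ends lay 0.239 ± 0.0262% of the covered length in control and 0.201 ± 0.0698% in siORCA (SD, n = 2 each; exact permutation p = 0.667). With the stricter list the shares were 0.442 ± 0.112% and 0.254 ± 0.0865%, and the groups did not overlap (SD, n = 2 each; exact permutation p = 0.33, the smallest this design allows). In the full lists the value of siORCA 1, 0.250%, lay between those of the controls, 0.221% and 0.258%, and that of siORCA 2 was 0.152%. Without siORCA 2 the difference changed sign, to 0.0112 percentage points above control.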

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

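The tests in this part were chosen after the results were seen, except the split counts of regions and the alternatives planned before. Those include the matched list size, the stricter list and the leave-one-out values. The bounds by which explanations were weighed were all written afterwards.

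Peaks on the mitochondrial genome entered the list totals, overlaps and merged regions, but no comparison of the main part looked at them alone. They covered 100% of it in control 1, 85.1% in control 2, 48.7% in siORCA 1 and 73.7% in siORCA 2, where peaks cover 1.88% to 2.77% of the whole assembly. They stood out as signal outside the nuclear chromosomes. The covered length was 15332 ± 1749 bp in control and 10144 ± 2927 bp in siORCA (SD, n = 2 each; exact permutation p = 0.33, the smallest this design allows).

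Peak coverage was higher in siORCA on chromosome 10 from 43 Mb and on chromosome 1 from 143 Mb, where the real split called 2 windows and the highest of the other splits 78 (2 of 3 splits called at least as many, too few splits for a share under 0.05). Longer siORCA lists as the whole cause are argued against on chromosome 10, where the window stayed past the threshold at matched list size (log2 1.14, SE 0.16, adjusted p = 0.0302 in limma, in a range of 1.63e-05 to 0.999 over alternatives), while on chromosome 1 the call ended (log2 1.11, SE 0.25 before and 1.26, SE 0.20 after, adjusted p = 0.0686, range 0.00442 to 1.00) and the point stays open. After cyclic loess, which removes a trend with window density, the log2 differences were 0.89 (SE 0.17) and 1.17 (SE 0.23), against 0.95 (SE 0.20) and 1.11 (SE 0.25) before, but no window passed (adjusted p = 0.129). A 95% interval above 0, which both differences have, was the bound first set against this trend as the whole cause, and it was replaced, after the values were seen, by staying past the threshold as for list size, and by that bound the trend stays open. More DNA copies of these stretches in the siORCA-transfected cells could raise all bins alike, but the 83.3% of bins that were higher on chromosome 10 decide nothing, since the stretch was joined from windows that were higher, and more origins in one domain could do the same, as could a different genomic DNA background for each group, if the caller used one, and these cannot be told apart without the genomic DNA samples.

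More regions were gained than lost in siORCA. The ratio depended on list length: it fell from 3.25 to 1.62 with lists at the same covered length, and was 13.4 with the stricter list, where siORCA lists keep more of their peaks. The 1.62 was above the 1.38 of the highest other split, but 3 splits are too few to decide, and a remaining part played by list size or depth cannot be told apart from an effect of the siRNA.

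Control 1 resembled siORCA 2, and control 2 resembled siORCA 1, in how peaks spread over dense and sparse windows, but only in part of the measures. The split that joins them called 78 windows against the real 2, and 16 against 1 at matched list size, and separated 16 of 23 chromosomes against 6 (12 against 9 at matched list size, 7.67 by chance), which points to a structure of the samples other than the groups. The densest 313 of 3132 windows held 38.8% and 41.5% of covered length in the first pair, against 33.4% and 35.3% in the second. At matched list size these were 38.8% and 42.6% against 34.9% and 39.3%, so the pairs no longer separated. Both siORCA samples (39.3% and 42.6%) then lay above both controls (38.8% and 34.9%), a split that 4 samples cannot tell from chance. The group difference over windows also rose with window density, r = 0.516 and, at matched list size, 0.575. The same correlation was −0.620 and −0.432 for the second pair minus the first, and 0.191 and 0.0442 for the other split. Over windows, control 2 correlated best with siORCA 1 (r = 0.964). Control 1 correlated less with siORCA 2 (0.948) than with control 2 (0.951) or siORCA 1 (0.964). A difference in library fragment length is a candidate explanation: the smallest peak, which the caller ties to fragment length, was 17.5 bp wider in the first pair on average (106 and 103 bp against 92 and 82 bp), but 4 samples are too few to decide. Labels exchanged between the groups were also weighed: control 2 and siORCA 1 shared the least of all pairs (Jaccard index 0.185), barely under the 0.187 of the 2 controls, while median fold (3.82 and 3.94 against 4.51 and 4.21) and the window on chromosome 10 from 43 Mb (31.2 and 29.8 kb against 71.5 and 70.7 kb) followed the labels, but that window was picked for doing so and 4 samples are too few, so the point stays open.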

How the results depend on the processing

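Cyclic loess and the crossed block were chosen after seeing the data. For the 8 named windows, 24 of 96 values under alternatives (both blocks and no filter) equal the original by construction, and the other 72 had its direction, in windows chosen for their difference. Windows called as higher fell from 2 to 1 at matched list size and to 0 with the stricter list, median centring, the pseudocount 5 times larger, 250 kb windows and cyclic loess; the cause was not tested. Leaving out a replicate gave 0 to 18 windows higher and 0 to 64 lower, with the extremes without siORCA 1. With the replicate number as a block, 0 windows were called. The same-numbered samples deviated in opposite directions (r = −0.458 over windows, −0.384 at matched list size). The labels give only replicate numbers, so whether same-numbered samples were prepared together is unknown, and the result with this block is not set aside. The crossed block called 3 windows higher and 1 lower. For single values a block cannot move the mean difference (55852 peaks, 12.3 Mb), and the exact p within blocks was 1.0 for both. The difference in peak number, siORCA minus control, turned to −4579 at matched list size, where lengths were made equal, and ran from −10022 (without siORCA 1) to 121725 with a replicate left out. That in covered length ran from 1.24 Mb (without siORCA 1) to 23.4 Mb (without siORCA 2). With a replicate left out, the median width difference ran from −35.5 to 9.5 bp, at 0.5 bp without control 1 and 9.5 bp without siORCA 1. The chromosome end share difference ran from −0.0875 to 0.0112 percentage points with a replicate left out (0.0112 without siORCA 2). It was −0.187 with the stricter list, −0.0049 at matched list size and −0.0002 when computed as a share of peaks. The median fold difference was 0.243 with the stricter list and 1.09 at matched list size. The Jaccard index within minus between groups ran from −0.0686 (without siORCA 1) to 0.0787 (without control 1), where 1 group has no pair left. Gained regions numbered 17838 at matched list size and 50145 to 177147 with a replicate left out. Lost regions numbered 1974 with the stricter list and 16423 to 104756 with a replicate left out; fewer samples set fewer conditions. Regions in all 4 numbered 24764 with the stricter list and 14820 when each sample had to cover most of the region. Chromosomes without overlap ranged from 11 to 18 with a replicate left out. Merged over gaps of 1 kb, 20834 regions were gained, fewer than the 23008 of control 2 and siORCA 1 only. No alternative for genes, gene lists or annotation shares was run, and the block was not run for overlap, regions or chromosome shares, which have no fitted model. Depth is unknown and limits every statement on list size.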

Other observations

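The test over chromosomes was chosen after the windows on chromosomes 1 and 10 were seen. Its criterion was changed from both siORCA samples above both controls to the group means, after the values under both were known. The reason given was that the first is met by chance too seldom to test a rise on most chromosomes.

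Regions shared by all 4 samples lay mostly in windows dense in peaks, a density that the same peaks define: 68.0% were in the densest of 5 equal groups of windows, against 33.2% of regions found in 1 sample only. Gained regions were there in 47.8% of cases and lost regions in 37.4%. The crossing pairs gave 45.5% (control 1 and siORCA 2 only) and 40.3% (control 2 and siORCA 1 only). By chromosome, peaks covered 55.4 ± 8.43 kb per Mb on chromosome 19 and 52.5 ± 7.50 kb on chromosome 22, against 6.03 ± 2.27 kb on chromosome X, 9.33 ± 3.07 kb on chromosome 13 and 10.0 ± 2.80 kb on chromosome 4 (SD, n = 4 samples).

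The called window on chromosome 10 begins close to the end of that chromosome's longest stretch without any peak, 39.5 to 42.0 Mb. The one on chromosome 1 lies farther from its own, 121.6 to 126.7 Mb. However, the stretch on chromosome 1 from 142 Mb directly follows a block of windows with too little coverage to enter the window test. That block holds some peaks, so it was not counted as peak-free. The flank tested below therefore does not reach the called window on chromosome 1. A hypothesis was that origins beside the longest peak-free stretch may rise on most chromosomes after ORCA siRNA. Within 5 Mb of it, the siORCA mean lay above the control mean on 12 of 22 chromosomes, or 54.5% (exact binomial 95% interval 32.2 to 75.6%), so the test does not decide. Both siORCA samples lay above both controls on 5 chromosomes (1, 2, 4, 10 and 19) and below them on chromosomes 14 and 20, where chance gives 3.7 in each direction. Chromosome 16 had no window with enough coverage there. The interval treats chromosomes as independent. It also counts chromosome 10, whose called window lies in the tested flank and was seen before the hypothesis was written.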
